A study of Canis lupus familiaris with 29 samples.

How the data were processed

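Total RNA from the cells was isolated with a Qiagen RNeasy kit, copied to cDNA, amplified by in vitro transcription and labelled with biotin, per the submitters' labels. The deposited values are log2 levels per probe set, and per the submitters' processing notes MAS5, Affymetrix Expression Console 1.1, GCRMA and Partek 6.6 were used, without the role or order of each. The values were used as the authors deposited them, without further normalization. The table holds 43035 probe sets, of which 111 are Affymetrix controls, and of the other 42924 those that reached log2 5 in at least 3 of the 29 arrays were tested, 16571 in all. Gene names are those of the platform's annotation table, checked by gene identifier. No genome build was used here, so no positions are given.

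Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit on the means of 8 groups over all 29 arrays and eBayes with a trend of the variance on the mean level. The tests are two-sided and moderated, and p-values were adjusted with the Benjamini-Hochberg method over 16571 probe sets within each comparison, with a threshold of 0.05. There were 12 comparisons. Those against control, against HGF and between inhibitors compare 2 groups, and 3 comparisons test the difference of an effect between cultures. A change by HGF counted as opposed where the inhibitor comparison passed in the other direction. The number expected from independent calls is the product of the counts divided by the number tested.

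Gene lists, 24 in all, were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation and with limma's fry, on 1 probe set per gene, the one with the highest mean. List p-values were adjusted over the 24 lists within a comparison. The counts adjusted over the list alone use the same limma p-values, adjusted within the list. Lists, comparisons, the main model and most alternatives were fixed before the data were examined.

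Genes named by rule are those that passed, with a single gene symbol that is not a LOC number and with no overlap between the arrays of both groups. The 10 largest changes in each direction were taken for HGF in each culture and for 3D against 2D control, the 5 largest for each inhibitor and for the difference of the HGF effect, and the 3 largest for the other comparisons. Up to 3 members of each described list were taken in each direction, and a fixed set was always given. Some genes the rule names are not printed. Of the fixed set, SPRY4, ETV4, ETV5, FOSL1, MMP14 and CDH1 were not tested, since their highest level in any array was 1.92, 2.34, 2.72, 2.35, 2.44 and 3.84, and PLAUR and CYP1A1 had no probe set that names a single gene. A gene's probe sets can differ, and among 3633 genes with more than 1 tested probe set 85 had calls in opposite directions for HGF in 3D and 51 in 2D.

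The RNA-quality index of an array is the mean of 3 differences between control probe sets, 3′ minus 5′ for ACTB and GAPDH and 3′ minus middle for EEF1A1. Its differences between groups were tested with exact two-sided permutation tests. A second index is the median over 2664 genes of the centred within-gene difference between 2 kinds of probe set. Across the 29 arrays its Pearson correlation with the RNA-quality index was -0.789.

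Alternatives were no filter and a stricter filter (log2 6), eBayes without trend, the arrays of the compared groups alone, quantile normalization once more, median centring of each array, limma array weights, the replicate number as a block, a 2-fold threshold, the mean of a gene's probe sets for lists, and each array left out in turn. Whether the replicate numbers pair arrays was examined from the correlation of their deviations from the group mean. Both RNA-quality covariates, leaving out 3D HGF replicates 1 and 4, and leaving out each array for the lists were added after the data were seen. Data were simulated with 1 spread per probe set over all arrays and uncorrelated genes. For true log2 differences of 0.5, 1 and 2 the model recovered 41.8%, 83.6% and 100% of probe sets for HGF in 3D. It recovered 50.7%, 91.0% and 100% for HGF in 2D and 22.4%, 67.2% and 93.9% for the difference. False calls were 5.06%, 6.40% and 2.40% of all calls, and only the 1 shifted list of 24 was called.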

Results

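Messenger RNA was measured with 29 Affymetrix canine arrays in MDCK cells, a line of dog kidney epithelial cells, grown flat (2D) or in collagen (3D). Cells were left untreated (control), given hepatocyte growth factor (HGF), the ligand of the receptor MET, or given HGF with PD-98059 or U0126. Both compounds inhibit MEK, the kinase that activates ERK, and they differ in chemical structure. Each culture had 4 control and 4 HGF arrays, PD-98059 was added in 4 arrays in 2D and 3 in 3D, and U0126 in 3 arrays in each culture. Their number limits the precision of every value. Doses and times are not given in the sources used here. Values are log2 differences between group means ± the standard error from limma, with the fold beside them. A gene or gene list that rose or fell passed an adjusted p threshold of 0.05. A mean level below log2 5 is called dim, and a fold from a dim level rests on background signal. The p-values measure differences against the spread between these arrays, which may be partly technical.

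The arrays of both inhibitors in 2D overlapped on components 1 to 3 of a principal component analysis, which held 47.9%, 19.7% and 9.16% of the variance. The 3D HGF arrays differed most from each other, with a lowest correlation between 2 arrays of 0.964 against 0.987 or more in every other group. Their mean deviation from the group mean was 0.336 on the log2 scale, and replicate 1 lay farthest, at 0.445. An RNA-quality index, the mean difference between 3′ and 5′ or middle control probe sets of ACTB, GAPDH and EEF1A1, was 1.93 ± 0.238 (SD, n = 4) in 3D control, 1.68 ± 0.583 (SD, n = 4) in 3D HGF, 1.44 in 2D control (n = 4) and 0.838 ± 0.0476 (SD, n = 4) in 2D HGF. The index differed between the arms of the HGF, PD-98059 and U0126 comparisons in 2D and between both controls, each with exact two-sided permutation p = 0.0286, the smallest the design allows, and 0.0643 after Benjamini-Hochberg adjustment over 9 comparisons. In the 3D comparisons of HGF, PD-98059 and U0126 the exact p was 0.514, 0.914 and 0.886.

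**Figure D1:**
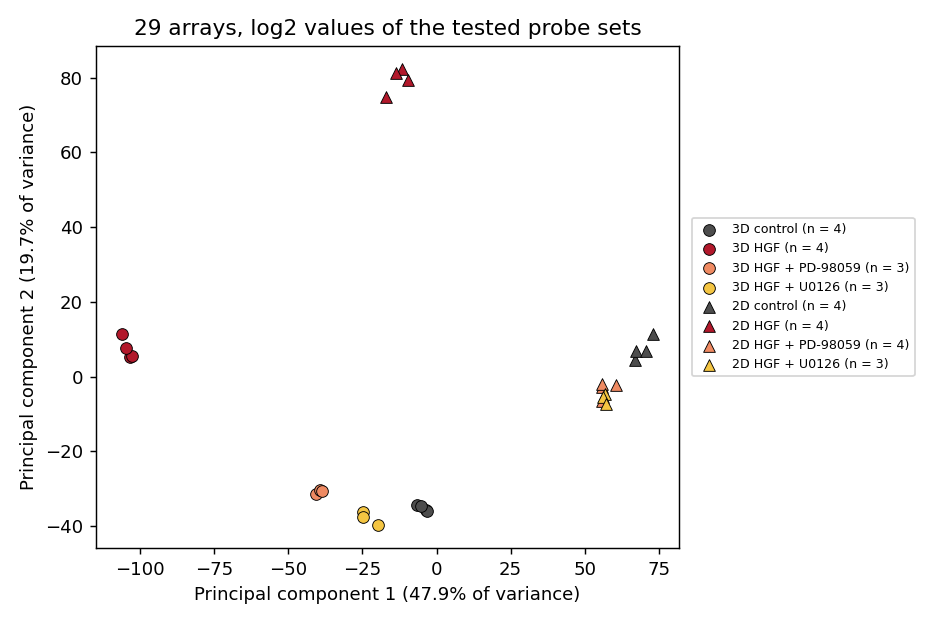
Scores of the 29 arrays on principal components 1 and 2 of the log2 levels of the tested probe sets (axes in score units, each point 1 array, colour for the group). Component 1 holds 47.9% and component 2 holds 19.7% of the variance, and the 3D HGF arrays lie at the low end of component 1, between -106 and -103.

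What HGF changed in cells grown in collagen was asked by comparing 4 HGF with 4 control arrays in 3D. The largest rise was in TIMP1, an inhibitor of matrix metalloproteinases, which rose 270-fold (8.08 ± 0.28). MMP1, the interstitial collagenase, rose 127-fold (6.99 ± 0.44) from a dim 3.29 to 10.28. EREG, a ligand of the EGF receptor, rose from a dim 3.02 to 7.02, and GPC3, a heparan sulfate proteoglycan, rose 13.7-fold (3.78 ± 0.17). The stress kinase MAP3K5 rose by 4.62 ± 0.56 and the DNA repair helicase FANCM by 3.55 ± 0.47, from dim levels, 3.69 to 8.30 and 4.93 to 8.48. TENT5A (5.03 ± 0.22), MALL (4.28 ± 0.14) and LRRC59 (4.07 ± 0.33) also rose from dim levels, which went from 3.81 to 8.84, 4.25 to 8.53 and 4.02 to 8.09. The chemokine CXCL8 fell 235-fold (-7.88 ± 0.17), from 11.03 to 3.15, which is dim. The chemokines CCL7 (-6.02 ± 0.14), CXCL10 (-5.89 ± 0.14) and CCL2 (-5.75 ± 0.25) fell with it, CCL7 to a dim level, from 9.58 to 3.55, and CXCL10 to a dim level, from 8.98. ACTA2, the smooth muscle actin, fell 43.6-fold (-5.45 ± 0.38), from 10.36 to 4.92, and PDZK1, a scaffold of apical transporters, fell 41.6-fold (-5.38 ± 0.20), from 10.07 to 4.69, both to dim levels. RANBP3L (-6.52 ± 0.13) and ARHGAP24 (-5.74 ± 0.18) fell to dim levels as well, from 10.64 to 4.12 and 8.49 to 2.75. CLDN2, a claudin that forms cation pores in tight junctions, fell by 2.60 ± 0.20 to a dim level, from 6.14 to 3.53.

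Among the genes of the ERK pathway output list, 11 of 12 tested genes rose and 0 fell (11 and 0 when adjusted over the list alone). Examples are the phosphatases DUSP5 (2.15 ± 0.20) and DUSP6 (0.82 ± 0.09), the cyclin CCND1 (1.93 ± 0.12) and EPHA2 (2.76 ± 0.34, from a dim 2.44 to 5.20), with camera adjusted p = 0.000734. In the cell cycle list 24 of 28 tested genes rose and 0 fell (24 and 0 when adjusted over the list alone), among them the replication factor CDC6 (2.78 ± 0.18), CCNE1 (1.84 ± 0.11) and the mitotic kinesin KIF11 (1.73 ± 0.20). For that list camera adjusted p = 4.03e-06, and adjusted p = 0.204 with an estimated correlation. In the cholesterol synthesis list 11 of 15 tested genes rose and 0 fell (11 and 0 when adjusted over the list alone). INSIG1 changed by 1.54 ± 0.13, CYP51A1 by 1.02 ± 0.07 and FDFT1 by 0.97 ± 0.08, and camera adjusted p = 0.00423, and adjusted p = 0.241 with an estimated correlation. In the inflammatory and interferon response list 1 of 14 tested genes rose and 13 fell (1 and 13 when adjusted over the list alone), and the gene that rose was PTGS2 (1.55 ± 0.23), the inducible prostaglandin synthase. The median of this list was -2.48, with camera adjusted p = 5.39e-06. In the primary cilium list 1 of 24 tested genes rose and 20 fell (1 and 20 when adjusted over the list alone), with median -1.13 and camera adjusted p = 1.26e-05. DYNC2H1, the motor of retrograde ciliary transport, changed by -3.03 ± 0.19, its cargo adaptor IFT140 by -2.81 ± 0.36 and the transition zone protein TMEM67 by -2.79 ± 0.15, while IFT20 rose by 0.60 ± 0.11.

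Of 16571 tested probe sets, 4879 rose and 5404 fell with HGF in 3D, of which 1639 and 2340 changed at least 2-fold. The split turned to 5875 and 4799 after median centring, 5753 and 5257 after quantile normalization, 8717 and 5461 without a filter and 4839 and 4808 without 3D HGF replicates 1 and 4. FN1 rose by 0.48 ± 0.13. MET (0.28 ± 0.16, adjusted p = 0.141), MMP13 (0.57 ± 0.34, adjusted p = 0.150), VIM (0.13 ± 0.09, adjusted p = 0.249), PLAU (0.22 ± 0.25, adjusted p = 0.452) and CDH16 (-0.04 ± 0.15, adjusted p = 0.841) did not pass. MET passed without 3D HGF replicate 1 (adjusted p = 0.00938), with array weights (0.0314), after median centring (0.0320) and after quantile normalization (0.0444), in a range of 0.00938 to 0.616 over its alternatives. VIM passed after median centring (0.0129, range 0.0129 to 0.473), and MMP13 with the compared groups alone (0.00562, range 0.00562 to 0.334).

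What HGF changed in flat cultures was asked in the same way with 4 HGF and 4 control arrays in 2D. TIMP1 rose 213-fold (7.74 ± 0.28), and MMP13, another collagenase, rose 138-fold (7.11 ± 0.34) from a dim 3.79 to 10.90. The exonuclease ISG20 rose 142-fold (7.15 ± 0.10), from a dim 1.65 to 8.80, and the desmosomal cadherin DSG3 rose 109-fold (6.76 ± 0.17), from a dim 2.25 to 9.01. S100A2 rose 98.6-fold (6.62 ± 0.11), the cell cycle inhibitor CDKN1A 62.9-fold (5.97 ± 0.19) and PTGS2 54.3-fold (5.76 ± 0.23). TFPI2 (6.22 ± 0.23) and ENTPD3 (5.67 ± 0.27) rose from dim levels, which went from 3.58 to 9.80 and 3.89 to 9.57. PDZK1 fell 44.7-fold (-5.48 ± 0.20) and RIPPLY1 fell 36.0-fold (-5.17 ± 0.21). CLTRN fell 62.3-fold (-5.96 ± 0.31), the secretin receptor SCTR 28.1-fold (-4.81 ± 0.21) and CLDN2 20.7-fold (-4.37 ± 0.20), each to a dim level, from 10.21 to 4.25, 8.03 to 3.22 and 8.49 to 4.12. GABRA3 (-5.53 ± 0.94), DRC1 (-5.18 ± 0.18), DHRS3 (-4.58 ± 0.50) and AK8 (-4.41 ± 0.24) fell to dim levels, from 10.35 to 4.81, 8.71 to 3.53, 9.41 to 4.83 and 7.84 to 3.43. DEPTOR, an inhibitor of the kinase mTOR, fell by 4.49 ± 0.43.

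In the ERK pathway output list 9 of 12 tested genes rose and 1 fell (10 and 1 when adjusted over the list alone). DUSP5 changed by 3.08 ± 0.20, CCND1 by 2.25 ± 0.12, DUSP6 by 1.07 ± 0.09 and camera adjusted p = 0.000140. EGR1, an immediate early transcription factor in this list, fell by 1.72 ± 0.27. In the matrix protease list 9 of 13 tested genes rose and 0 fell (9 and 0 when adjusted over the list alone), SERPINE2 rose by 4.95 ± 0.12 and MMP1 by 2.41 ± 0.44 from a dim 3.21 to 5.63 (3.07 and 1.82 without 2D HGF replicates 3 and 4), with camera adjusted p = 0.000140. In the mesenchymal marker list 6 of 10 tested genes rose and 0 fell (6 and 0 when adjusted over the list alone). The transcription factor SNAI2 rose by 5.35 ± 0.12, S100A4 by 2.40 ± 0.12, FN1 by 0.75 ± 0.13 and VIM by 0.62 ± 0.09. The mesenchymal list had camera adjusted p = 0.00708, and adjusted p = 0.174 with an estimated correlation. In the actin cytoskeleton and YAP target list 9 of 11 tested genes rose and 1 fell (10 and 1 when adjusted over the list alone). ACTN1 changed by 2.48 ± 0.27, FLNA by 1.67 ± 0.18 and CCN2 by -1.32 ± 0.14. The test gave camera adjusted p = 0.00708, and ACTB is both in this list and in the RNA-quality index. In the cell cycle list 25 of 28 tested genes rose and 1 fell (25 and 1 when adjusted over the list alone). CDC6 changed by 4.20 ± 0.18 and TTK by 3.61 ± 0.25 (from dim 4.22 to 8.42 and 4.76 to 8.37), AURKA by 2.89 ± 0.14 and camera adjusted p = 3.76e-09.

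In the hypoxia and glycolysis list 25 of 26 tested genes rose and 0 fell (25 and 0 when adjusted over the list alone), with median 1.42 and camera adjusted p = 9.41e-12. The prolyl hydroxylase EGLN3 rose by 4.45 ± 0.39 (dim 4.81 to 9.26), the lactate transporter SLC16A3 by 4.29 ± 0.29 (dim 4.90 to 9.19) and PFKFB3 by 3.91 ± 0.17. The RNA-quality index moved by -0.601, mainly in ACTB (3.52 to 1.77, with glycolytic GAPDH 0.53 to 0.36 and EEF1A1 0.26 to 0.39). In the cholesterol synthesis list 13 of 15 tested genes rose and 0 fell (14 and 0 when adjusted over the list alone). INSIG1 changed by 3.62 ± 0.13 and FDPS by 2.36 ± 0.10, and camera adjusted p = 4.36e-08. In the unfolded protein and amino acid stress list 13 of 14 tested genes rose and 1 fell (13 and 1 when adjusted over the list alone), MTHFD2 rose by 3.74 ± 0.30 and DDIT3 by 2.88 ± 0.15, and VLDLR changed by -0.60 ± 0.12. The stress list had camera adjusted p = 3.86e-05, and adjusted p = 0.140 with an estimated correlation. In the primary cilium list 1 of 24 tested genes rose and 19 fell (1 and 19 when adjusted over the list alone), with median -1.06, DYNC2H1 at -1.78 ± 0.19, IFT140 at -1.96 ± 0.36 and camera adjusted p = 5.72e-06. In 2D 4353 probe sets rose and 4832 fell, 1510 and 1708 of them at least 2-fold, and the split turned to 4756 and 4511 after median centring. MET rose by 1.12 ± 0.16. CDH16 (0.24 ± 0.15, adjusted p = 0.206) and PLAU (0.09 ± 0.25, adjusted p = 0.791) did not pass.

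**Figure D2:**
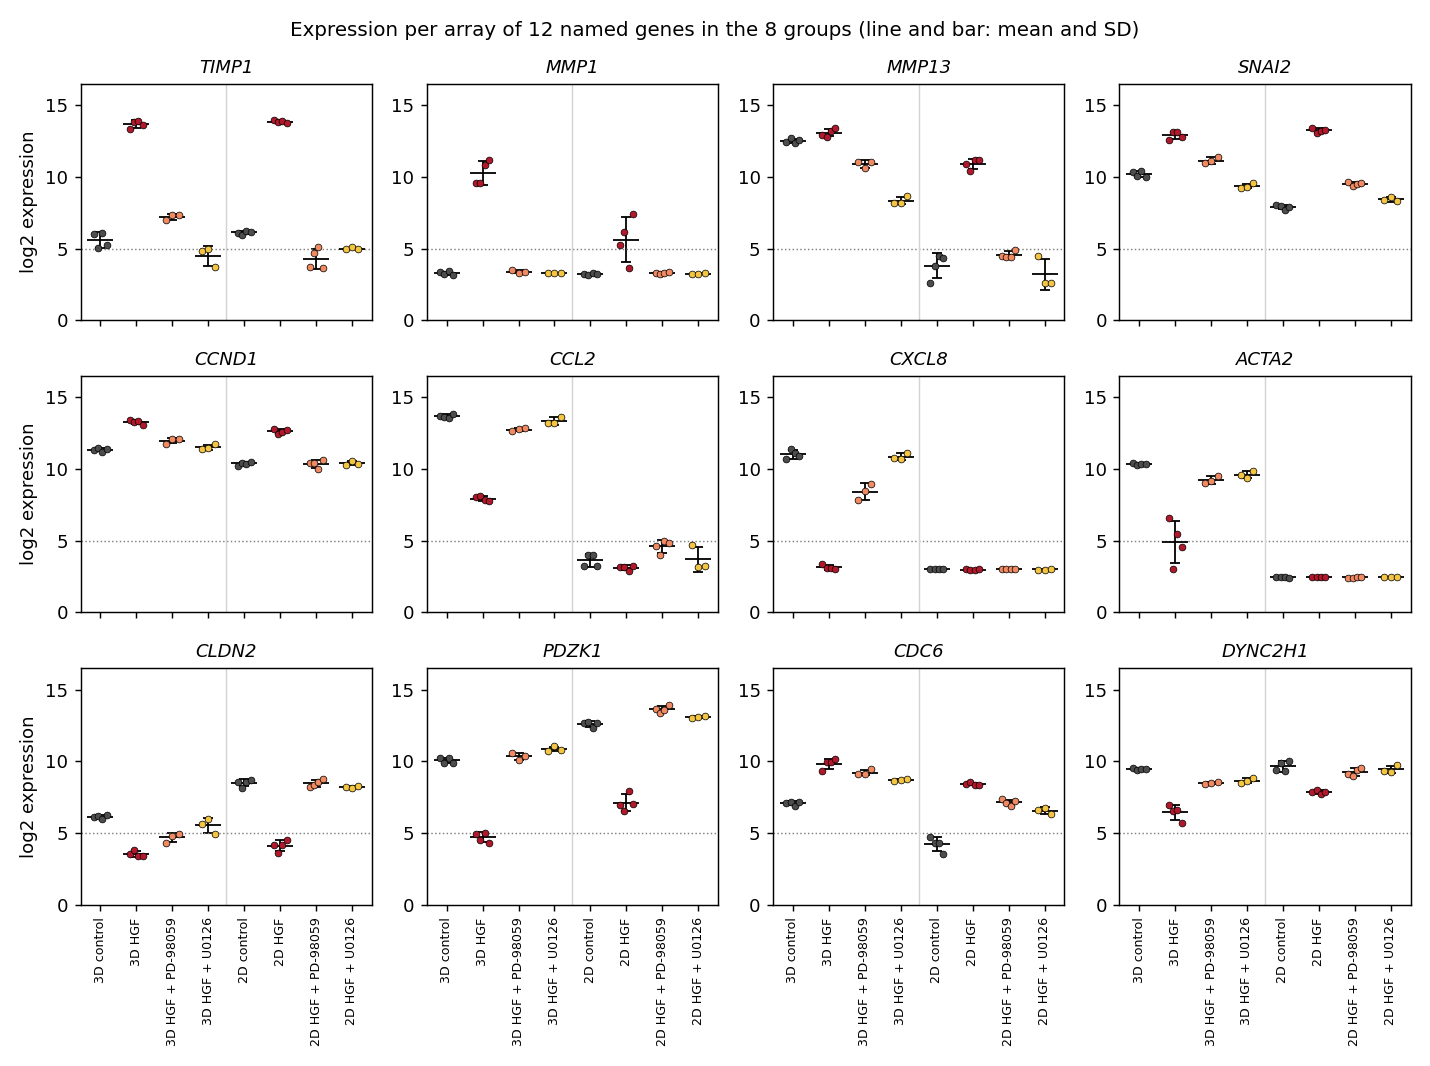
Mean log2 level of 12 genes in the 8 groups (vertical axis in log2 units, bars for 1 SD over 3 or 4 arrays, dotted line at the dim level of 5). TIMP1 goes from 5.59 to 13.66 with HGF in 3D and from 6.12 to 13.85 in 2D, and CCL2 from 13.70 to 7.95 in 3D.

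Whether the HGF effect differed between cultures was tested as the 3D effect minus the 2D effect, over 16 arrays. The chemokines CXCL8 (-7.86 ± 0.23) and CCL7 (-6.05 ± 0.19), TFPI2 (-7.48 ± 0.33), ISG20 (-7.24 ± 0.14) and MMP13 (-6.53 ± 0.48) had strongly negative differences, of uncertain size. CXCL8 and CCL7 were dim in both 2D groups and in 3D HGF, ISG20 was dim outside 2D HGF, and TFPI2 and MMP13 were dim in 2D control. STEAP2 (4.97 ± 0.39), L3MBTL2 (5.44 ± 0.97), EML4 (4.85 ± 0.77) and KIDINS220 (4.65 ± 1.43) had positive ones, with STEAP2 dim in 2D HGF and L3MBTL2 and KIDINS220 in 3D control. KIDINS220 did not pass without 3D HGF replicates 1 and 4 (adjusted p = 0.0736, range 0.00171 to 0.0736 over its alternatives). MMP1 rose more in 3D, by 4.58 ± 0.63, from dim levels in both cultures, and CLDN2, which fell to dim levels in both, had a difference of 1.77 ± 0.28, while MET (-0.84 ± 0.23) and VIM (-0.49 ± 0.13) had a smaller effect in 3D. CCND1 (-0.32 ± 0.17, adjusted p = 0.114), FN1 (-0.27 ± 0.18, adjusted p = 0.230), CDH16 (-0.28 ± 0.22, adjusted p = 0.313), DUSP6 (-0.25 ± 0.13, adjusted p = 0.115) and PLAU (0.13 ± 0.35, adjusted p = 0.785) did not pass. DUSP6 passed after quantile normalization (adjusted p = 0.00630) and with the RNA-quality index as covariate (0.0338), in a range of 0.00630 to 0.325.

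In the inflammatory list 13 of 14 genes had a lower effect in 3D and 0 a higher one (13 and 0 when adjusted over the list alone), with camera adjusted p = 2.11e-09. Of the 14, 5 (CCL2, CXCL10, CXCL8, SAA1 and VCAM1) were dim in both 2D groups, where they could not fall, and of the other 9 genes 8 had a lower effect. For the actin and YAP target list these counts were 9 and 0 of 11 (9 and 0 when adjusted over the list alone), with camera adjusted p = 0.000646. In the hypoxia and glycolysis list 21 of 26 had a lower effect in 3D and 0 a higher one (21 and 0 when adjusted over the list alone). EGLN3 (dim in both 3D groups and in 2D control) had a difference of -4.43 ± 0.55 and ADM of -3.73 ± 0.21. The hypoxia list had camera adjusted p = 2.11e-09, and adjusted p = 0.0991 with an estimated correlation. A lower effect in 3D was also seen in 10 of 14 stress genes and a higher one in 2 (10 and 2 when adjusted over the list alone), with DDIT3 at -3.45 ± 0.21. For cholesterol genes these counts were 11 and 1 of 15 (13 and 1 when adjusted over the list alone), with INSIG1 at -2.08 ± 0.18. The tests gave camera adjusted p = 0.00116, and adjusted p = 0.302 with an estimated correlation for stress, and camera adjusted p = 0.000646, and adjusted p = 0.161 with an estimated correlation for cholesterol. In the mesenchymal list 6 of 10 had a lower effect and 1, ZEB1, a higher one (6 and 1 when adjusted over the list alone). ACTA2, dim in both 2D groups and in 3D HGF, had a difference of -5.45 ± 0.54, and camera adjusted p = 0.0272, and adjusted p = 0.302 with an estimated correlation. In the oxidative phosphorylation list 10 of 24 had a higher effect and 1 a lower one (10 and 1 when adjusted over the list alone). CYC1 had a difference of 2.04 ± 0.17, and camera adjusted p = 0.00335, and adjusted p = 0.460 with an estimated correlation.

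The difference passed for 8011 probe sets, 3645 higher and 4366 lower. Of the probe sets called in each culture, 2414 rose in both and 3010 fell in both, against 1282 and 1576 if the calls were independent, and 522 and 611 went opposite ways, against 1423 and 1420. Across the 16571 probe sets the HGF effects had Pearson r = 0.512 and Spearman rho = 0.479, and probe sets are not independent replicates.

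How untreated cells in collagen differed from flat cells was asked with 4 arrays of each. CCL2 was 1074-fold higher in 3D (10.07 ± 0.25), from a dim 3.63 to 13.70, and CXCL8 was 260-fold higher (8.02 ± 0.17), from a dim 3.01 to 11.03. CCL7 (6.50 ± 0.14), CXCL10 (5.91 ± 0.14) and the cytokine CSF2 (6.47 ± 0.31) were higher in 3D too, from dim 3.07 to 9.58, 3.08 to 8.98 and 3.77 to 10.24. MMP13 was 422-fold higher (8.72 ± 0.34) and the gelatinase MMP9 71.8-fold higher (6.17 ± 0.24), from dim 3.79 to 12.51 and 2.72 to 8.88. ACTA2 was 241-fold higher (7.91 ± 0.38) and the activin subunit INHBA 62.8-fold higher (5.97 ± 0.35), from dim 2.45 to 10.36 and 3.74 to 9.71. BIRC3, an inhibitor of apoptosis, was higher by 5.25 ± 0.15. The GABA receptor subunit GABRA3 (-5.16 ± 0.94), CLTRN (-4.41 ± 0.31) and the organic cation transporter SLC22A2 (-3.61 ± 0.42) were lower in 3D. SCTR (-4.89 ± 0.21), SYT13 (-4.34 ± 0.17), SBSN (-4.20 ± 0.24), TBC1D5 (-4.05) and the alkaline phosphatase ALPL (-3.60 ± 0.19) were lower and dim in 3D. Their levels from 2D to 3D were 8.03 to 3.14, 7.13 to 2.79, 8.85 to 4.65, 6.50 to 2.45 and 6.46 to 2.86.

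In the inflammatory list 12 of 14 tested genes rose and 1 fell (12 and 1 when adjusted over the list alone) in 3D, with median 1.93 and camera adjusted p = 6.63e-10. C3, a complement component, fell by 0.65 ± 0.20. In the cell cycle list 25 of 28 tested genes rose and 0 fell (25 and 0 when adjusted over the list alone). TTK changed by 3.23 ± 0.25 and BUB1B by 3.12 ± 0.31 (from dim 4.76 to 7.99 and 4.92 to 8.04), and camera adjusted p = 1.07e-15. In the actin and YAP target list 10 of 11 tested genes rose and 1 fell (10 and 1 when adjusted over the list alone). ANKRD1 changed by 3.80 ± 0.22 (from a dim 2.36 to 6.15), TPM4 by 1.18 ± 0.09 and camera adjusted p = 0.000106. In the matrix protease list 8 of 13 tested genes rose and 1 fell (8 and 1 when adjusted over the list alone). SERPINE2 changed by 2.15 ± 0.12 and PLAU by 1.58 ± 0.25, and camera adjusted p = 0.00200. In the mesenchymal list 8 of 10 tested genes rose and 1 fell (8 and 1 when adjusted over the list alone). TAGLN changed by 4.04 ± 0.22 (from a dim 4.77 to 8.81), SNAI2 by 2.31 ± 0.12, FN1 by 0.74 ± 0.13 and VIM by 0.50 ± 0.09. Its test gave camera adjusted p = 5.09e-05, and adjusted p = 0.0515 with an estimated correlation. In the cholesterol list 12 of 15 tested genes rose and 0 fell (12 and 0 when adjusted over the list alone). FDPS changed by 1.97 ± 0.10, INSIG1 by 1.41 ± 0.13 and camera adjusted p = 1.34e-06. In the hypoxia and glycolysis list 2 of 26 tested genes rose and 19 fell (2 and 19 when adjusted over the list alone). ADM changed by -2.94 ± 0.15, SLC16A3 by -3.02 ± 0.29 and EGLN3 by -2.58 ± 0.39, the last 2 dim in both cultures, from 4.90 to 1.88 and 4.81 to 2.23. Its test gave camera adjusted p = 3.76e-08, and adjusted p = 0.0744 with an estimated correlation. In the primary cilium list 2 of 24 tested genes rose and 14 fell (2 and 14 when adjusted over the list alone). IFT52 changed by -1.17 ± 0.10 and BBS7 by -1.08 ± 0.12, and camera adjusted p = 0.00505, and adjusted p = 0.0861 with an estimated correlation. In the ribosomal protein list 1 of 29 tested genes rose and 22 fell (1 and 25 when adjusted over the list alone). RPL13 changed by -0.91 ± 0.10 and RPLP1 by -0.82 ± 0.10, and camera adjusted p = 5.09e-05, and adjusted p = 0.523 with an estimated correlation. The RNA-quality index was higher in 3D control by 0.493.

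In this comparison 3907 probe sets were higher and 4755 lower in 3D, 1054 and 1476 of them at least 2-fold. The split turned to 6666 and 5363 without a filter, 4648 and 4498 after quantile normalization and 4607 and 4302 after median centring. DUSP6 rose by 0.44 ± 0.09 and CCND1 by 0.96 ± 0.12, EGR1 changed by -2.64 ± 0.27, and CLDN2 changed by -2.35 ± 0.20. MET (-0.24 ± 0.16, adjusted p = 0.234), CDH16 (0.09 ± 0.15, adjusted p = 0.658) and MMP1 (0.07 ± 0.44, adjusted p = 0.907, dim, 3.21 to 3.29) did not pass, and MET passed with the compared groups alone (adjusted p = 0.0362, range 0.0362 to 0.783). Markers of other cell types were measured with it. Of 13 fibroblast markers on the array, COL5A1 alone reached log2 8 in 3D control (8.09, and 7.51 in 2D control), with COL1A1 at 3.38, COL1A2 at 2.86 and COL3A1 at 3.72. Of 11 leukocyte markers CD74 alone did (12.79, and 12.54 in 2D control), and of 10 endothelial markers FLT1 alone did (10.47, and 9.77 in 2D control).

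Which HGF changes MEK inhibition opposed in collagen was asked with 3 arrays for each inhibitor against the 4 HGF arrays. No group had an inhibitor alone, so effects apart from HGF cannot be excluded. With PD-98059, MMP1 fell 119-fold (-6.89 ± 0.48, to a dim level, from 10.28 to 3.38), TIMP1 87.1-fold (-6.45 ± 0.30) and GPC3 15.1-fold (-3.92 ± 0.19). MAP3K5 changed by -4.59 ± 0.60 (8.30 to a dim 3.71) and ANTXR2 by -3.79 ± 0.35. MGST1 rose 76.8-fold (6.26 ± 0.31), ACKR3 75.2-fold (6.23 ± 0.20) and PDZK1 50.6-fold (5.66 ± 0.22), the last 2 from dim 4.24 to 10.47 and 4.69 to 10.35. CXCL8 (5.27 ± 0.18) and CCL7 (4.84 ± 0.15) rose from dim levels, 3.15 to 8.42 and 3.55 to 8.39. With U0126, TIMP1 fell 581-fold (-9.18 ± 0.30), MMP1 with it (-6.98 ± 0.48), TENT5A 27.5-fold (-4.78 ± 0.24) and MALL 25.2-fold (-4.65 ± 0.15), each to a dim level, from 13.66 to 4.48, 10.28 to 3.30, 8.84 to 4.06 and 8.53 to 3.88. MMP13, which did not pass for HGF, fell by 4.76 ± 0.37. CXCL8 rose 208-fold (7.70 ± 0.18), PDZK1 71.6-fold (6.16 ± 0.22) and RANBP3L 39.2-fold (5.29 ± 0.15), from dim 3.15 to 10.85, 4.69 to 10.85 and 4.12 to 9.41. CCL2 rose by 5.40 ± 0.27 and FILIP1L by 5.59 ± 0.24.

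In the ERK pathway output list 0 of 12 tested genes rose and 10 fell (0 and 11 when adjusted over the list alone) with PD-98059 and 0 of 12 tested genes rose and 11 fell (0 and 12 when adjusted over the list alone) with U0126. DUSP5 changed by -1.58 ± 0.21 and -2.65 ± 0.21, CCND1 by -1.30 ± 0.13 and -1.76 ± 0.13, DUSP6 by -0.34 ± 0.10 and -1.08 ± 0.10 and EPHA2 by -2.75 ± 0.37 and -2.80 ± 0.37 (to dim levels, 5.20 to 2.45 and 5.20 to 2.40), in that order of inhibitor. The tests gave camera adjusted p = 3.20e-06 for PD-98059, and camera adjusted p = 4.02e-06 for U0126, and the fall of DUSP6 with PD-98059 did not pass with the compared groups alone (adjusted p = 0.0579, range 8.04e-05 to 0.0579). In the matrix protease list 1 of 13 tested genes rose and 6 fell (1 and 6 when adjusted over the list alone) with PD-98059 and 1 of 13 tested genes rose and 7 fell (1 and 7 when adjusted over the list alone) with U0126, and the gene that rose was MMP9 (2.19 ± 0.26 with PD-98059). For this list camera adjusted p = 0.00415 for PD-98059, and for U0126 camera adjusted p = 0.0129, and adjusted p = 0.0539 with an estimated correlation. In the primary cilium list 18 of 24 tested genes rose and 0 fell (19 and 0 when adjusted over the list alone) with PD-98059 and 17 of 24 tested genes rose and 0 fell (17 and 1 when adjusted over the list alone) with U0126, the former with camera adjusted p = 0.000182 and the latter with camera adjusted p = 3.37e-05. DYNC2H1 rose by 2.03 ± 0.21 and TMEM67 by 1.89 ± 0.16 with PD-98059, and DYNC2LI1 rose by 2.31 ± 0.19 and IFT80 by 2.88 ± 0.41 with U0126. In the inflammatory list 8 of 14 tested genes rose and 1 fell (8 and 1 when adjusted over the list alone) with PD-98059, with ICAM1 at -0.70 ± 0.16, and camera adjusted p = 0.0449, and adjusted p = 0.134 with an estimated correlation. That call was lost without 3D HGF replicate 3 (0.0647), 3D HGF replicate 4 (0.0590), 3D HGF + PD-98059 replicate 2 (0.0697) or 2D HGF + PD-98059 replicate 4 (0.0590), and with either RNA-quality covariate (0.0613 and 0.0743) and with replicate number as a block (0.0529), range 0.0228 to 0.0743. With U0126 8 of 14 tested genes rose and 2 fell (9 and 2 when adjusted over the list alone), CXCL10 rose by 3.02 ± 0.15 from a dim level to 6.12, and camera adjusted p = 0.00278.

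In the list of aryl hydrocarbon receptor targets, which holds detoxifying enzymes, 2 of 4 tested genes rose and 0 fell (4 and 0 when adjusted over the list alone) with PD-98059 and 4 of 4 tested genes rose and 0 fell (4 and 0 when adjusted over the list alone) with U0126. CYP1B1 rose by 2.11 ± 0.22 and 2.09 ± 0.22. For PD-98059 camera adjusted p = 0.0449, and adjusted p = 0.200 with an estimated correlation, and for U0126 camera adjusted p = 0.0184, and adjusted p = 0.111 with an estimated correlation. The PD-98059 call was lost without 3D HGF replicate 1 (0.0522), 2 (0.0506) or 3 (0.0559), 3D HGF + PD-98059 replicate 1 (0.0778) or 2D HGF + PD-98059 replicate 4 (0.0590). It was also lost with a stricter filter (0.0564) and with either RNA-quality covariate (0.0631 and 0.0743), range 0.0134 to 0.0778. With U0126 the cholesterol list had 10 of 15 genes that fell and 0 that rose (11 and 0 when adjusted over the list alone), INSIG1 at -1.49 ± 0.14 and FDFT1 at -0.98 ± 0.09, and camera adjusted p = 0.00141, and adjusted p = 0.111 with an estimated correlation. In the NRF2 target list 7 of 11 tested genes rose and 1 fell (7 and 1 when adjusted over the list alone). The transporter ABCC2 rose by 2.89 ± 0.23 (from a dim 3.06 to 5.95) and the ferritin chain FTH1 by 1.96 ± 0.09, and camera adjusted p = 0.0394, and adjusted p = 0.404 with an estimated correlation. It was lost without 3D HGF replicate 4 (0.0524) and without 3D HGF replicates 1 and 4 (0.0574), in a range of 0.00206 to 0.0574. With PD-98059 6 rose and 1 fell (camera adjusted p = 0.0532, range 0.00287 to 0.0926), and the list passed without a filter (0.00287), after quantile normalization (0.0241) or median centring (0.0387), and without 3D HGF replicate 2 (0.0417), 3D HGF + PD-98059 replicate 3 (0.0479), 2D HGF + PD-98059 replicate 2 (0.0489) or 3D HGF + U0126 replicate 2 (0.0468) or 3 (0.0478). The endothelial list had FLT1 as its single tested gene, a receptor of VEGF, which changed by -2.35 ± 0.11 with PD-98059 and by -2.37 ± 0.11 with U0126. Its list call, with camera adjusted p = 0.0140, and for U0126 camera adjusted p = 0.0394, and adjusted p = 0.0971 with an estimated correlation, was lost without a filter (0.214 and 0.245) and with the mean of a gene's probe sets (0.0690 and 0.125), and for U0126 with the RNA-quality covariates (0.0513 and 0.0520) and without 3D HGF replicates 1 and 4 (0.0549), ranges 0.00856 to 0.214 and 0.0254 to 0.245.

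With PD-98059 in 3D 4408 probe sets rose and 2557 fell, and with U0126 4214 and 3952, which turned to 3712 and 4992 after median centring. The PD-98059 split was 3485 and 3954 after median centring and 3935 and 3589 after quantile normalization, and 4365 probe sets passed with the compared groups alone. Of 10283 probe sets changed by HGF in 3D, PD-98059 opposed 5707 (55.5%) and moved 238 further in the same direction. U0126 opposed 6677 (64.9%) and moved 167 further. With the HGF arrays split 2 and 2, 147 to 425 and 94 to 537 moved further. The opposed PD-98059 set held 2139 that HGF raised and 3568 that it lowered, 3256 and 2898 after median centring and 2946 and 3255 after quantile normalization, and the U0126 set 3066 and 3611. Both effects use the same HGF arrays, which by itself favours opposed calls. Independent calls would give 2190 and 2538, 20 simulations with no effect at all, and so no HGF changes to oppose, gave 0, and splitting the HGF arrays 2 and 2 left 4463 to 4819 and 5260 to 5883. Of the probe sets that HGF changed at least 2-fold, the median share of the change left was 40.5% ± 3.55 (SD over 3 arrays) with PD-98059 and 29.5% ± 4.41 (SD over 3 arrays) with U0126. FN1 changed by -1.11 ± 0.14 and -1.11 ± 0.14, PLAU by -1.74 ± 0.27 and -1.70 ± 0.27, MMP13 by -2.20 ± 0.37 with PD-98059, and CLDN2 rose by 1.16 ± 0.22 (dim, 3.53 to 4.69) and 1.99 ± 0.22 (from a dim 3.53 to 5.53). VIM fell by 0.47 ± 0.10 with U0126.

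MET fell by 0.74 ± 0.18 with U0126, a call lost with the compared groups alone (0.0919, range 3.04e-06 to 0.0919), and was -0.37 ± 0.18 with PD-98059 (adjusted p = 0.102), which passed without 3D HGF replicate 1 (0.00729) and in 5 other settings (0.0161 to 0.0220), range 0.00729 to 0.406. VIM was -0.26 ± 0.10 with PD-98059 (adjusted p = 0.0424), and it did not pass without 3D HGF replicate 1 (0.0628), 2 (0.110) or 3 (0.107), or without 3D HGF + PD-98059 replicate 1 (0.0727), 2 (0.132) or 3 (0.0711), and not in 5 other settings (0.0586 to 0.0930), range 0.000433 to 0.132. CDH16 was -0.34 ± 0.17 (adjusted p = 0.108) and 0.17 ± 0.17 (adjusted p = 0.432), and passed after median centring (0.0444, range 0.0444 to 0.560) for PD-98059 and with array weights (0.0298, range 0.0298 to 0.814) for U0126.

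The same question was asked in flat cultures with 4 PD-98059 and 3 U0126 arrays against 4 HGF arrays. TIMP1 fell 755-fold with PD-98059 (-9.56 ± 0.28, to a dim level, 13.85 to 4.29) and 463-fold with U0126 (-8.85 ± 0.30). ISG20 changed by -7.17 ± 0.10 and -7.16 ± 0.11, DSG3 by -6.65 ± 0.17 and -6.51 ± 0.18 and MMP13 by -6.33 ± 0.34 and -7.70 ± 0.37, all to dim levels, 8.80 to 1.63 and 8.80 to 1.64, 9.01 to 2.36 with PD-98059 for DSG3, 10.90 to 4.57 and 10.90 to 3.21. PDZK1 rose 90.9-fold (6.51 ± 0.20) and 62.3-fold (5.96 ± 0.22), and CLTRN rose by 5.54 ± 0.31 and 6.02 ± 0.33 from a dim 4.25 to 9.79 and 4.25 to 10.27. RIPPLY1 rose by 5.29 ± 0.21, and GPR18 (4.92 ± 0.21) rose from a dim 2.38 to 7.31, with PD-98059. STEAP2 (4.82 ± 0.30) rose from a dim 3.99 to 8.81, and ARHGAP24 by 4.65 ± 0.20, with U0126.

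In the ERK pathway output list 0 of 12 tested genes rose and 11 fell (0 and 11 when adjusted over the list alone) with PD-98059 and 0 of 12 tested genes rose and 12 fell (0 and 12 when adjusted over the list alone) with U0126. DUSP5 changed by -3.49 ± 0.20 and -4.10 ± 0.21, EMP1 by -3.32 ± 0.22 and -3.37 ± 0.24 to dim levels, 7.68 to 4.36 and 7.68 to 4.31, and EGR1 by -2.70 ± 0.27 and -2.72 ± 0.29, also dim, 7.11 to 4.41 and 7.11 to 4.39. The tests gave camera adjusted p = 1.57e-06 for PD-98059, and camera adjusted p = 2.84e-07 for U0126. In the matrix protease list 0 of 13 tested genes rose and 9 fell (0 and 9 when adjusted over the list alone) and 0 of 13 tested genes rose and 10 fell (0 and 10 when adjusted over the list alone). SERPINE2 changed by -3.26 ± 0.12 and -3.84 ± 0.13, and camera adjusted p = 7.38e-05 and camera adjusted p = 6.78e-05. In the mesenchymal list 1 of 10 tested genes rose and 7 fell (1 and 7 when adjusted over the list alone) and 1 of 10 tested genes rose and 7 fell (1 and 7 when adjusted over the list alone). SNAI2 changed by -3.73 ± 0.12 and -4.82 ± 0.13, S100A4 by -3.04 ± 0.13 with U0126. The gene that rose was TGFBI (3.28 ± 0.13 and 3.13 ± 0.14, from a dim level, 4.89 to 8.17 and 4.89 to 8.02), a secreted matrix protein. The tests gave camera adjusted p = 0.00865, and adjusted p = 0.186 with an estimated correlation for PD-98059, and camera adjusted p = 0.0110, and adjusted p = 0.194 with an estimated correlation for U0126. In the actin and YAP target list 1 of 11 tested genes rose and 10 fell (1 and 10 when adjusted over the list alone) and 1 of 11 tested genes rose and 8 fell (1 and 9 when adjusted over the list alone). ACTN1 changed by -3.71 ± 0.27 (to a dim level, 8.15 to 4.44) and -2.99 ± 0.29, TPM4 by -1.56 ± 0.09 and -1.42 ± 0.09 and FLNA by -1.75 ± 0.18 and -1.20 ± 0.19, and camera adjusted p = 0.000710 and camera adjusted p = 0.0124.

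In the hypoxia and glycolysis list 0 of 26 tested genes rose and 25 fell (0 and 25 when adjusted over the list alone) with PD-98059 and 0 of 26 tested genes rose and 26 fell (0 and 26 when adjusted over the list alone) with U0126. EGLN3 changed by -3.07 ± 0.39 and -3.97 ± 0.42 and PFKFB3 by -3.34 ± 0.17 and -2.89 ± 0.19. The lists gave camera adjusted p = 4.27e-10 and camera adjusted p = 1.77e-10. The RNA-quality index rose with these arms by 0.527 and 0.477. In the cholesterol list 0 of 15 tested genes rose and 12 fell (0 and 12 when adjusted over the list alone) and 0 of 15 tested genes rose and 12 fell (0 and 12 when adjusted over the list alone). INSIG1 changed by -2.40 ± 0.13 and -3.09 ± 0.14 and FDFT1 by -1.18 ± 0.08 and -1.46 ± 0.09. The tests gave camera adjusted p = 0.000217, and adjusted p = 0.0723 with an estimated correlation for PD-98059, and camera adjusted p = 2.76e-06 for U0126. In the stress list 2 of 14 tested genes rose and 10 fell (2 and 12 when adjusted over the list alone) and 1 of 14 tested genes rose and 11 fell (1 and 11 when adjusted over the list alone). DDIT3 changed by -3.44 ± 0.15 and -3.38 ± 0.16, MTHFD2 by -2.76 ± 0.30 and -3.04 ± 0.32, and VLDLR by 1.38 ± 0.12 and 1.41 ± 0.13. For this list camera adjusted p = 0.000233, and adjusted p = 0.186 with an estimated correlation for PD-98059, and camera adjusted p = 0.000189, and adjusted p = 0.191 with an estimated correlation for U0126. In the primary cilium list 17 of 24 tested genes rose and 1 fell (18 and 1 when adjusted over the list alone) and 19 of 24 tested genes rose and 2 fell (19 and 2 when adjusted over the list alone). IFT140 changed by 2.23 ± 0.36 and 2.00 ± 0.39, and camera adjusted p = 7.38e-05 and camera adjusted p = 0.000122.

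With U0126 the junction list passed without a filter (adjusted p = 0.0276, range 0.0276 to 0.438) and the oxidative phosphorylation list after quantile normalization (0.00892, range 0.00892 to 0.235). Of 20 basement membrane and integrin genes 6 rose and 10 fell with PD-98059 (6 and 11 when adjusted over the list alone). The laminin chain LAMA3 changed by -4.42 ± 0.11 and ITGA6 by -4.06 ± 0.08, and camera adjusted p = 0.0205, and adjusted p = 0.332 with an estimated correlation. Of 28 epithelial junction genes 6 rose and 15 fell with PD-98059 (6 and 15 when adjusted over the list alone). CLDN4 changed by -2.58 ± 0.21, JUP by -2.06 ± 0.17 and CLDN2 by 4.34 ± 0.20 (from a dim 4.12 to 8.46), and camera adjusted p = 0.0200, and adjusted p = 0.175 with an estimated correlation. That call was lost with the mean of a gene's probe sets (0.0997, range 0.00348 to 0.0997). Of 24 oxidative phosphorylation genes 11 rose and 1 fell with PD-98059 (11 and 1 when adjusted over the list alone). NDUFB5 changed by 1.22 ± 0.10, and camera adjusted p = 0.0443, and adjusted p = 0.568 with an estimated correlation. It was lost without 2D HGF replicate 4 (0.0588) or 2D HGF + PD-98059 replicate 3 (0.0735) or 4 (0.0776), with a stricter filter (0.0514) and with the RNA-quality index as covariate (0.0849), range 0.00437 to 0.0849. With U0126 4 of 4 tested genes rose and 0 fell (4 and 0 when adjusted over the list alone) in the aryl hydrocarbon receptor list, with CYP1B1 at 2.72 ± 0.22 and TIPARP at 1.49 ± 0.41, and camera adjusted p = 0.0343, and adjusted p = 0.165 with an estimated correlation. It was lost without 2D HGF replicate 1 (0.0505) or 2D HGF + U0126 replicate 1 (0.0546), without 3D HGF replicates 1 and 4 (0.0510) and with the within-gene index as covariate (0.0523), range 0.0160 to 0.0546. FLT1 changed by -2.88 ± 0.10 with PD-98059 and -2.57 ± 0.11 with U0126, and its list, with camera adjusted p = 0.0268, and adjusted p = 0.0723 with an estimated correlation, and for U0126 camera adjusted p = 0.0360, and adjusted p = 0.0822 with an estimated correlation, was lost without a filter (0.381 and 0.530) and with the mean of a gene's probe sets (0.0774 and 0.0930), and for U0126 with the within-gene index (0.0542) and without 3D HGF replicates 1 and 4 (0.0527), ranges 0.0194 to 0.381 and 0.0288 to 0.530.

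In 2D 4566 probe sets rose and 4124 fell with PD-98059, and 4269 and 4026 with U0126, which turned to 4263 and 4597 and to 4050 and 4526 after median centring. Of 9185 probe sets changed by HGF, PD-98059 opposed 6736 (73.3%, 3230 raised and 3506 lowered by HGF) and U0126 6841 (74.5%, 3344 and 3497), and 146 and 74 moved further in the same direction. Independent calls would give 2415 and 2302, and splitting the HGF arrays 2 and 2 left 5421 to 5601 and 5504 to 5732, with 76 to 132 and 41 to 71 further. The median share of the HGF change left was 13.9% ± 2.66 (SD over 4 arrays) and 11.7% ± 3.97 (SD over 3 arrays). MET changed by -1.55 ± 0.16 and -1.52 ± 0.18, CCND1 by -2.28 ± 0.12 and -2.22 ± 0.13, FN1 by -1.57 ± 0.13 and -0.93 ± 0.14 and VIM by -0.62 ± 0.09 and -0.78 ± 0.10, while CLDN2 rose by 4.07 ± 0.22 from a dim 4.12 to 8.19 with U0126. MMP1 changed by -2.34 ± 0.44 and -2.37 ± 0.48 to dim levels, 5.63 to 3.29 and 5.63 to 3.25. PLAU fell by 1.26 ± 0.25 with PD-98059, and with U0126 it was -0.71 ± 0.27 (adjusted p = 0.0294).

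That PLAU call was lost without 2D HGF replicate 1 (0.0721), 3 (0.0848) or 4 (0.0617), without 2D HGF + U0126 replicate 1 (0.131), without a filter (0.0765) and with the RNA-quality index as covariate (0.358), range 0.00500 to 0.358. DUSP6 fell by 0.72 ± 0.10 with U0126 and was -0.18 ± 0.09 with PD-98059 (adjusted p = 0.103), which passed without 2D HGF + PD-98059 replicate 4 (0.0320) and in 4 other settings (0.0171 to 0.0458), range 0.0171 to 0.311. CDH16 was -0.20 ± 0.15 (adjusted p = 0.307) and 0.00 ± 0.17 (adjusted p = 0.997), and passed for PD-98059 without 2D HGF + PD-98059 replicate 2 (0.0425, range 0.0425 to 0.952).

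Whether both inhibitors acted differently was tested directly, with 3 arrays of each in 3D and 3 U0126 against 4 PD-98059 arrays in 2D. In 3D U0126 left lower levels of DKK3, an inhibitor of Wnt signalling (-3.82 ± 0.27, dim with U0126, 8.33 to 4.51), TIMP1 (-2.74 ± 0.32, 7.22 to 4.48) and MMP13 (-2.55 ± 0.40). It left higher levels of CLTRN (3.21 ± 0.36, 4.07 to 7.28) and CXCL10 (2.57 ± 0.16, 3.55 to 6.12), each dim with PD-98059. In 2D DKK3 (-3.13 ± 0.25, 7.85 to 4.73) was lower with U0126 and dim there, and FGFBP1 differed by -2.27 ± 0.36. IL13RA2 (1.64 ± 0.22, 3.98 to 5.62) and CLIC3 (1.35 ± 0.18, 4.90 to 6.25) were higher. SNAI2, chosen after its values were seen, differed by -1.78 in 3D and -1.09 in 2D. FOS, an early target of ERK, differed by -1.06 ± 0.11 in 3D and by -0.57 ± 0.10 in 2D, and DUSP6 by -0.74 (95% interval -0.96 to -0.52) and -0.54 ± 0.10. DUSP5 was lower in 3D (-1.07 ± 0.23).

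In the cholesterol list 10 of 15 genes were lower with U0126 in 3D and 4 in 2D (12 and 11 when adjusted over the list alone). INSIG1 differed by -0.84 ± 0.15 and -0.69 ± 0.14, and camera adjusted p = 2.19e-07 and camera adjusted p = 5.93e-10. In the ERK list 6 of 12 were lower in 3D (6 when adjusted over the list alone), with camera adjusted p = 0.00717, and adjusted p = 0.0580 with an estimated correlation. In the inflammatory list 3 of 14 were higher and 1 lower in 3D (4 and 1 when adjusted over the list alone). CXCL8 differed by 2.43 ± 0.19, and camera adjusted p = 9.83e-05. In 2D 3 of 28 cell cycle genes were lower (12 when adjusted over the list alone). CCNB2 differed by -0.70 ± 0.13, and camera adjusted p = 1.44e-10. In the basement membrane list 3 of 20 were higher (6 when adjusted over the list alone), with the collagen chain COL4A1 at 0.90 ± 0.15, and camera adjusted p = 5.51e-08. The actin list in 2D had 0 of 11 genes passing alone and a median of 0.24, with camera adjusted p = 0.000575. The junction list in 2D had 1 of 28 higher (1 when adjusted over the list alone), with camera adjusted p = 0.00294, and adjusted p = 0.0896 with an estimated correlation.

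Other list calls were unstable. In 3D the actin list (camera adjusted p = 0.0430, and adjusted p = 0.138 with an estimated correlation), where 3 genes passed and the median (-0.02) and mean (0.30) differed in sign, was lost without 3D HGF replicate 1 (0.0539) or 3 (0.0511), 3D HGF + PD-98059 replicate 1 (0.0781) or 2 (0.0519), or 3D HGF + U0126 replicate 3 (0.115), without a filter (0.0516), with a stricter filter (0.0521) and after median centring (0.0591), range 0.0289 to 0.115. The stress list (camera adjusted p = 0.0405, and adjusted p = 0.485 with an estimated correlation) was lost without 3D HGF replicate 1 (0.0539), 3D HGF + PD-98059 replicate 1 (0.0589) or 2 (0.0519) or 3D HGF + U0126 replicate 2 (0.117), without 3D HGF replicates 1 and 4 (0.0505), without a filter (0.0679), and with a stricter filter (0.0524), quantile normalization (0.233) or the mean of a gene's probe sets (0.112), range 0.0162 to 0.233. The cilium list (camera adjusted p = 0.0367, and adjusted p = 0.262 with an estimated correlation) was lost without 3D HGF + PD-98059 replicate 1 (0.0515) or 2 (0.0519) or 3D HGF + U0126 replicate 2 (0.117), without a filter (0.0516) and with quantile normalization (0.0520), range 0.00851 to 0.117. The ribosomal list (camera adjusted p = 0.0367, and adjusted p = 0.647 with an estimated correlation) was lost without 3D HGF + PD-98059 replicate 1 (0.113) or 3D HGF + U0126 replicate 2 (0.192), and with a stricter filter (0.0521) or quantile normalization (0.769), range 0.000747 to 0.769. In 2D the ribosomal list (camera adjusted p = 0.00294, and adjusted p = 0.637 with an estimated correlation) was lost without 2D HGF + PD-98059 replicate 4 (0.171) and with quantile normalization (0.565), range 2.48e-05 to 0.565.

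In 3D 1957 probe sets passed, 495 higher and 1462 lower with U0126, and the split was 740 and 1111 after quantile normalization. The count was 1287 with the compared groups alone, 5447 with array weights, 1245 or 910 without 3D HGF + PD-98059 replicate 2 or 3, and 1066 or 1105 without 3D HGF + U0126 replicate 1 or 2. In 2D 269 passed, 140 higher and 129 lower. That count was 69 with the compared groups alone, 500 after quantile normalization, 519 with array weights, 471 and 520 with the RNA-quality covariates, and 167, 179 or 165 without 2D HGF + U0126 replicate 1, 2 or 3. With the compared groups alone, INSIG1 (0.0979), COL4A1 (0.0979), CCNB2 (0.166), FOS (0.0693), DUSP6 (0.135), IL13RA2 (0.0942) and FGFBP1 (0.129) did not pass in 2D. Over all alternatives of these 7 genes adjusted p ranged from 1.91e-05 to 0.166. A difference that misses the threshold does not show that the inhibitors act alike. The 95% interval lay within 2-fold in both directions for 14656 probe sets (88.4%) in 3D and 15506 (93.6%) in 2D. For MET the difference was -0.37 (-0.76 to 0.02) in 3D and 0.03 (-0.33 to 0.40) in 2D, for CYP1B1 -0.02 (-0.50 to 0.45) and 0.26 (-0.18 to 0.71), and for MMP1 -0.08 (-1.14 to 0.98) and -0.03 (-1.02 to 0.96).

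Whether each inhibitor's effect differed between cultures was tested as its 3D effect minus its 2D effect. For PD-98059 positive differences were in ISG20 (7.15 ± 0.14), TFPI2 (7.01 ± 0.34) and CXCL8 (5.24 ± 0.24), and negative ones in CLTRN (-5.09 ± 0.46), GPR18 (-5.01 ± 0.31) and STEAP2 (-4.79 ± 0.40). For U0126 they were CXCL8 (7.70 ± 0.25), ISG20 (7.14 ± 0.15) and TFPI2 (6.45 ± 0.36), and STEAP2 (-5.16 ± 0.42), MMP1 (-4.60 ± 0.68) and C9H17orf97 (-4.35 ± 0.32). Each of these had dim levels in at least 1 group compared, CXCL8 in each 2D group, so their sizes are uncertain. In the inflammatory list 10 of 14 genes had a more positive effect in 3D with PD-98059 and 9 with U0126 (11 and 9 when adjusted over the list alone), with camera adjusted p = 0.000210 and camera adjusted p = 9.01e-06. Without the same 5 dim genes these were 7 and 5 of 9. In the hypoxia and glycolysis list these counts were 21 and 19 of 26 (22 and 20 when adjusted over the list alone), with camera adjusted p = 2.52e-10, and adjusted p = 0.108 with an estimated correlation for PD-98059, and camera adjusted p = 2.30e-08, and adjusted p = 0.137 with an estimated correlation for U0126. In the stress list they were 10 and 8 of 14 (10 and 8 when adjusted over the list alone), with camera adjusted p = 0.000261, and adjusted p = 0.177 with an estimated correlation for PD-98059, and camera adjusted p = 0.00939, and adjusted p = 0.437 with an estimated correlation for U0126. In the cholesterol list they were 11 and 9 of 15 (13 and 9 when adjusted over the list alone), with camera adjusted p = 0.00114, and adjusted p = 0.164 with an estimated correlation for PD-98059, and camera adjusted p = 0.0188, and adjusted p = 0.409 with an estimated correlation for U0126. In the actin list they were 8 and 7 of 11 (8 and 8 when adjusted over the list alone), with camera adjusted p = 0.0327, and adjusted p = 0.117 with an estimated correlation for PD-98059, and camera adjusted p = 0.0324, and adjusted p = 0.137 with an estimated correlation for U0126. Both actin calls were lost without 3D HGF replicate 4 (0.0507 and 0.0545), the PD-98059 call with the RNA-quality index as covariate (0.0550) and the U0126 call without 3D HGF replicates 1 and 4 (0.0567), ranges 0.00160 to 0.0550 and 0.000776 to 0.0567. The difference passed for 5674 probe sets with PD-98059 (3644 higher and 2030 lower in 3D, 3383 and 2907 after quantile normalization) and 6052 with U0126 (3302 and 2750).

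Over 24 lists and 12 comparisons, 89 list results passed with camera's preset correlation and 43 of them with an estimated correlation. Those were ERK output, inflammatory and cilium for HGF in 3D, and ERK output, matrix, actin, cell cycle, cholesterol, hypoxia and cilium in 2D, with actin and inflammatory for the difference. For 3D against 2D control they were matrix, actin, cell cycle, cholesterol and inflammatory. In 3D they were ERK output, matrix, cilium and endothelial for PD-98059, and ERK output, inflammatory and cilium for U0126. In 2D they were ERK output, matrix, actin, hypoxia and cilium for PD-98059, and the same 5 and cholesterol for U0126. Between inhibitors they were cholesterol and inflammatory in 3D, and basement membrane, actin, cell cycle and cholesterol in 2D, and for each inhibitor's difference between cultures the inflammatory list. With fry, whose PValue tests whether a set's genes move, on balance, one way and whose PValue.Mixed tests for change in either direction, 202 passed, and neither compares a set with other genes. Median and mean differed in sign for HGF in 3D in the mesenchymal list (0.11 and -0.16, camera direction up), the hypoxia list (0.20 and -0.02) and the TGF-beta list (-0.02 and 0.29), none of which passed. For HGF in 2D the exocyst list had a median of -0.07 and a mean of -0.21 with camera direction up. Across the 12 comparisons 7 lists passed in none. Their smallest camera adjusted p was 0.108 for EGFR ligands and receptor tyrosine kinases, 0.173 for TGF-beta, BMP and Wnt output genes, 0.445 for kidney development factors, 0.164 for kidney tubule transport, 0.126 for exocyst and apical membrane traffic, 0.0715 for fibroblast markers and 0.0862 for leukocyte markers.

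**Figure D3:**
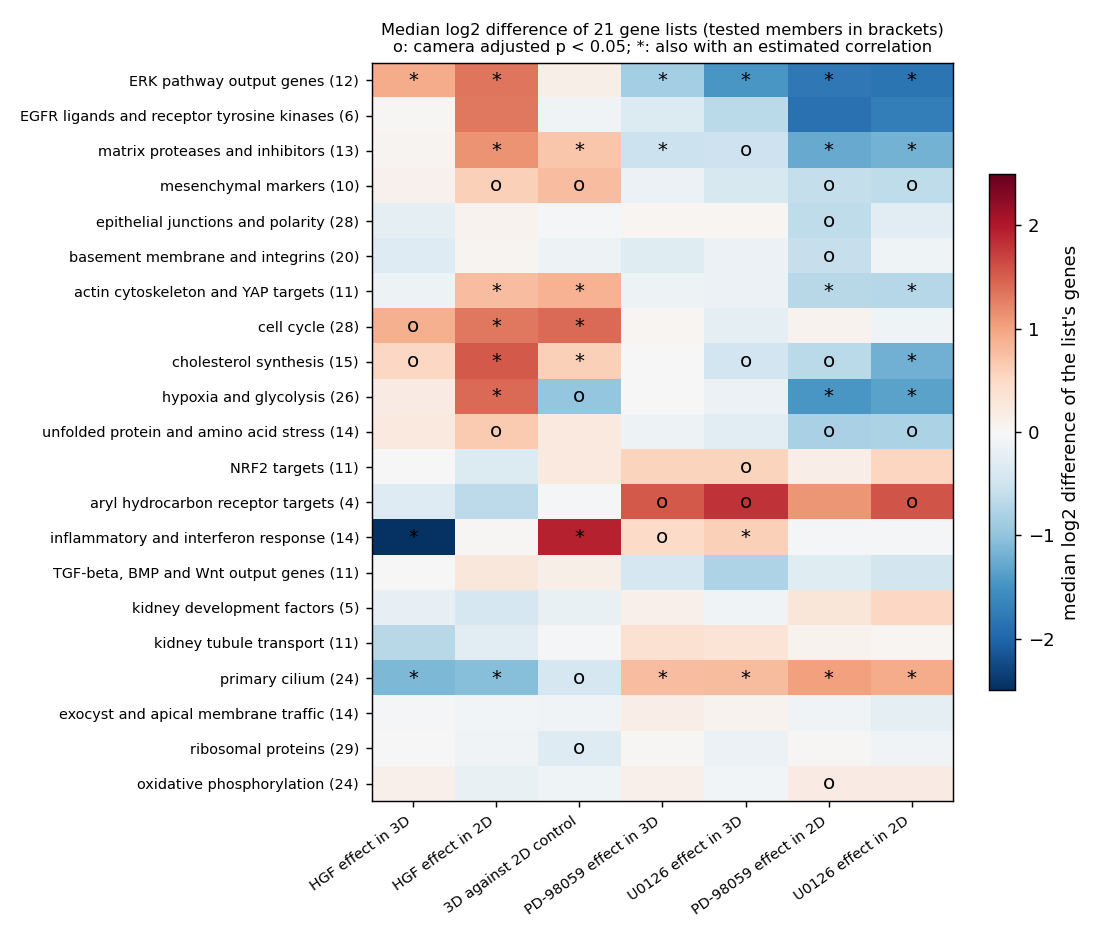
Median log2 difference of 21 gene lists (vertical) in 7 comparisons (horizontal), with the colour scale in log2 units. A circle marks camera calls with the preset correlation and a star those that also passed with an estimated correlation. The inflammatory list has a median of -2.48 for HGF in 3D and 1.93 for 3D against 2D control.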

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

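The tests of marker levels for fibroblasts and leukocytes were chosen only after the result was seen, as were both RNA-quality covariates. In groups of 4 arrays, Dixon's ratio, the gap of the farthest array to the nearest one divided by the whole range, was compared with its 95% critical value. It was above that value in 32 of 405 tests, and chance gives about 1 in 20.

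In 3D control the ratio was 0.847 for L3MBTL2 in replicate 1, 0.948 for FANCM, 0.871 for EMP1 and 0.849 for SLC22A2 in replicate 2, and 0.896 for FDFT1 in replicate 4. In 3D HGF it was 0.962 for FLNA, 0.898 for CXCL8, 0.877 for CLTRN and 0.848 for DUSP5 in replicate 1. In replicate 2 it was 0.981 for SLC16A3, 0.975 for ARHGAP24 and 0.862 for EML4, and in replicate 3 0.871 for DDIT3. In 2D control it was 0.863 for TGFBI in replicate 1. In replicate 3 of that group it was 0.979 for TBC1D5, 0.915 for DHRS3, 0.885 for L3MBTL2 and 0.876 for SLC22A2, and in replicate 4 0.943 for CSF2, 0.942 for ACTN1 and 0.892 for CYC1. In 2D HGF it was 0.884 for VLDLR and 0.832 for TIPARP in replicate 1, and 0.944 for IFT140, 0.910 for C9H17orf97 and 0.836 for DRC1 in replicate 2. It was 0.883 for CCL2 in replicate 3 and 0.836 for GPR18 in replicate 4. In 2D HGF + PD-98059 it was 0.980 for PLAU in replicate 2, 0.925 for CLDN4 in replicate 3, and 0.862 for MMP13 and 0.838 for VLDLR in replicate 4.

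The effect of HGF differed between 3D and 2D, by limma's test of the difference, for 8011 probe sets. The genes named with it were CXCL8 (-7.86), TFPI2 (-7.48), ISG20 (-7.24), MMP13 (-6.53), CCL7 (-6.05), ACTA2 (-5.45), EGLN3 (-4.43), ADM (-3.73), DDIT3 (-3.45), INSIG1 (-2.08), MET (-0.84) and VIM (-0.49) with a lower effect in 3D. Those with a higher one were L3MBTL2 (5.44), STEAP2 (4.97), EML4 (4.85), KIDINS220 (4.65), MMP1 (4.58), CYC1 (2.04) and CLDN2 (1.77). The PD-98059 effect differed for 5674 probe sets, among them ISG20 (7.15), TFPI2 (7.01), CXCL8 (5.24), CLTRN (-5.09), GPR18 (-5.01) and STEAP2 (-4.79). The U0126 effect differed for 6052, among them CXCL8 (7.70), ISG20 (7.14), TFPI2 (6.45), STEAP2 (-5.16), MMP1 (-4.60) and C9H17orf97 (-4.35), and dim levels make many of these sizes uncertain.

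Other splits of the same arrays were counted for each number of probe sets that passed. The real labels gave the highest count for HGF in 3D (10283, at most 4143 in the other splits, 1 of 35 as large) and in 2D (9185, at most 31, 1 of 35), and for 3D against 2D control (8662, at most 1, 1 of 35). The same holds for PD-98059 in 3D (6965, at most 5215, 1 of 35) and in 2D (8690, at most 7, 1 of 35), for U0126 in 3D (8166, at most 6645, 1 of 35) and in 2D (8295, at most 5861, 1 of 35), and for U0126 against PD-98059 in 2D (269, at most 109, 1 of 35). For U0126 against PD-98059 in 3D the 10 splits are too few (1957, at most 150, 1 of 10). For the differences between cultures 4 of 100 splits were as large for HGF (8011, at most 8611). For PD-98059 (5674, at most 8745) and U0126 (6052, at most 8432) 2 were. The others turned 1 culture's labels. Splits undo both effects, so they cannot test their difference. Mixing all groups cannot test opposition of HGF changes. PD-98059 gave 5707 in 3D (at most 3241) and 6736 in 2D (at most 1516), each 1 of 100. U0126 gave 6677 (at most 7323, 2 of 100) and 6841 (at most 444, 1 of 100).

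List counts leave chance open, as other splits often gave as many, for HGF in 2D up to 11 (at most 31 probe sets). Counted were lists for PD-98059 in 3D (6, at most 5, 1 of 35) and 2D (12, at most 12, 2 of 35), and U0126 in 3D (8, at most 7, 1 of 35) and 2D (10, at most 10, 2 of 35). The others were HGF in 3D (5, at most 6, 15 of 35) and 2D (9, at most 11, 10 of 35), the HGF difference (7, at most 12, 38 of 100), 3D against 2D control (9, at most 10, 15 of 35), U0126 against PD-98059 in 3D (7, at most 9, 2 of 10) and 2D (6, at most 8, 8 of 35), and the differences of PD-98059 (5, at most 12, 42 of 100) and U0126 (5, at most 12, 51 of 100).

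The 3D HGF arrays were spread wider than the other groups. Slopes of each probe set on the RNA-quality index, taken from the other 7 groups, correlated with the deviations of the 4 arrays from their mean at r = 0.58, -0.02, -0.27 and -0.52, a span of 1.1, and replicates 1 and 4 lie at the ends of the index. RNA 3′ bias of single arrays may account for a part of the spread, since removing those slopes took 7.49% of the variance (root mean square deviation 0.345 before, 0.332 after and 0.200 in the other groups). A stronger or weaker response to HGF in single arrays cannot be told apart from other sources, since the deviation of the farthest array correlated with the HGF effect in 2D at r = -0.123.

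Chemokine and interferon genes were higher in 3D control than in 2D control and lower with HGF in 3D. Fibroblasts and leukocytes in the 3D cultures would bring their abundant transcripts, and 1 fibroblast marker of 13 (COL5A1) and 1 leukocyte marker of 11 (CD74) reached log2 8 in 3D control. CCL2 stood at 13.7 there. Whether the marker probe sets detect such cells was not tested, so both stay open. With the index as covariate the list's median was 1.99, against 1.93 without it. This argues against RNA 3′ bias as the whole cause. A response of the MDCK cells to collagen is an untested hypothesis.

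Hypoxia and glycolysis genes were higher with HGF in 2D, and the difference between cultures passed. The list's median for HGF in 2D was 1.42, 1.39 with the within-gene index as covariate and 1.28 with the 3′ to 5′ index. After median centring or quantile normalization the smaller was 1.41. The 1.28 argues against RNA 3′ bias, as that index measures it, as the whole cause. The within-gene index overlapped between groups, and normalizing again cannot undo the authors' step, so neither decides. An HGF effect that differs between cultures stays open, as a hypothesis found and tested on the same data. With an estimated correlation adjusted p = 0.0276 for HGF in 2D and 0.0991 for the difference.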

How the results depend on the processing

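The tests with both RNA-quality covariates, without 3D HGF replicates 1 and 4, and with each array left out for the lists were chosen only after the data were seen. Of 489 named gene results, 0 that passed in the main or alternative run changed sign. Without a filter 21 no longer passed, with the compared groups alone 34 no longer passed and 2 newly did, and with the RNA-quality index as covariate these counts were 13 and 3. Leaving out 1 array moved 20 results by more than 1.5-fold, of ACTA2, EGLN3, FGFBP1, GABRA3, IFT80, KIDINS220, MAP3K5, MMP1, MMP13, SLC22A2 and TBC1D5. For the other settings run on all arrays, between 0 and 9 no longer passed and between 0 and 5 newly did. Of 89 list calls, 82 kept their call and direction without a filter, with 21 gained, 85 with quantile normalization (15 gained), 88 with median centring (6 gained) and 84 with the RNA-quality index as covariate (0 gained).

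A 2-fold threshold, which by construction lowers every count, left 3979 probe sets for HGF in 3D, 3218 in 2D and 3547 for their difference, 2530 for 3D against 2D control, 2065 and 2589 for PD-98059 and U0126 in 3D and 2856 and 2858 in 2D. It left 221 and 59 for U0126 against PD-98059 in 3D and 2D, 2285 and 2466 for the PD-98059 and U0126 differences, and 1709, 2114, 2095 and 2197 for the opposed changes in the order PD-98059 and U0126 in 3D and then in 2D. With only the arrays of the groups compared the count was 4365 for PD-98059 in 3D, 1287 for U0126 against PD-98059 in 3D and 69 in 2D. For the latter pair array weights gave 5447 and 519. In 2D quantile normalization gave 500 and the RNA-quality and within-gene covariates 471 and 520, and the cause was not tested.

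An estimated correlation left 43 list calls and fry gave 202. With fry the EGFR ligand list for HGF in 3D (adjusted p = 0.00825) and the NRF2 target list for HGF in 2D (adjusted p = 0.00970) turned direction, and the cause was not tested. Leaving out 1 array gave 9744 to 10407 for HGF in 3D, 8542 to 8805 in 2D, 7582 to 8347 for their difference and 8028 to 8220 for 3D against 2D control. It gave 5840 to 7106 and 7212 to 8396 for PD-98059 and U0126 in 3D, 8133 to 8385 and 7507 to 7937 in 2D, 910 to 2032 for U0126 against PD-98059 in 3D and 165 to 312 in 2D. In 3D it was 1245 and 910 without HGF + PD-98059 replicates 2 and 3, and 1066 and 1105 without HGF + U0126 replicates 1 and 2, and in 2D 167, 179 and 165 without HGF + U0126 replicates 1, 2 and 3. The PD-98059 and U0126 differences ranged from 4897 to 5977 and from 5270 to 6455, and list calls from 85 to 93.

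Without 3D HGF replicates 1 and 4 the count was 9647 for HGF in 3D, 7956 for the difference, 6246 and 8022 for PD-98059 and U0126 in 3D and 5129 and 6472 for the opposed changes. With the replicate number in the title as a replicate block the counts were 10236 for HGF in 3D and 9078 in 2D. Arrays with the same number were not alike in each pair, and the lowest correlation of their deviations was -0.200 for HGF in 3D and -0.117 in 2D.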

Other observations

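The motile cilium tests were set before their result was seen. The comparisons of HGF with an inhibitor against control and the test of the cell cycle rise were chosen only after the data were seen. Among genes of the axoneme, the motile core of cilia, 22 that had not been seen before were tested. With HGF in 2D 16 fell and 0 rose, with a median of -1.29, and 15 rose with PD-98059 (median 1.36) and 15 with U0126 (median 1.27). Examples for HGF in 2D are CCDC65 (-2.36 ± 0.29), ZMYND10 (-1.97 ± 0.13), a factor in dynein arm assembly, CFAP298 (-1.83 ± 0.15) and MNS1 (-1.79 ± 0.20), the second and last to or at dim levels. The largest camera adjusted p over the 3 comparisons was 3.45e-05, and adjusted p = 0.00274 with an estimated correlation. In 3D 12 fell and 1 rose with HGF.

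Some genes that HGF changed at least 2-fold stayed so with either inhibitor, each against control. These comparisons share their control arrays, which favours agreement. In 2D NQO1, a quinone reductase, rose by 3.21 ± 0.10 with HGF, 3.38 ± 0.10 with PD-98059 added and 3.68 ± 0.11 with U0126 added, and the spindle checkpoint kinase BUB1B by 2.89 ± 0.31, 3.35 ± 0.31 and 2.84 ± 0.33 from a dim 4.92. In the cell cycle list 25 genes were higher than control in 2D with HGF and PD-98059 (median 1.54) and 24 with HGF and U0126 (median 1.13). The median was 117% and 85.9% of that with HGF alone. It was 99.4% to 134% and 75.3% to 100% with the control arrays split 2 and 2, and stayed up. With PD-98059 and U0126, 3 and 7 genes were lower than with HGF alone. DUSP6 stood at 13.35 and 12.80 against 12.45 in 2D control, but DUSP5 and CCND1 fell back. Residual MEK activity was not tested, so why the rise stayed is open.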
